A study of Mus musculus with 6 samples.

How the data were processed

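RNA was extracted from the myometrium of 3 wild-type and 3 Tcf23 knockout pregnant mice, and poly(A)-selected, directional libraries were made, per the labels' protocols. The series design states that each library is from a different animal. The sample labels give E19.5 and the series design gestational day 19; which convention links them is not given in the sources used here.

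The authors deposited a table of raw counts per Ensembl gene for each library, and 1 table of normalized values for all 6. The submitters' processing notes name FastQC 0.73, HISAT2 2.2.1, HTSeq 0.9.1 and DESeq2 2.11.40.7 and the build mm10, with no role or order. The annotation release and the strand setting of the counting are not given in the sources used here. In the deposited normalized table each column is a signal equal to the raw count times 1 constant per library (0.804 to 1.26, largest relative deviation 9.9e-10), so it holds the same information on a common scale. Gene symbols and mm10 positions come from that table, whose start positions count from 0 and are printed counting from 1. Of 55055 identifiers, 54804 were found in GENCODE M21.

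Deposited counts were tested in R 4.3.3 with edgeR 4.0.16: genes kept by filterByExpr, TMM normalization, a quasi-likelihood fit with genotype as the term, and Benjamini-Hochberg adjusted p under 0.05. The fit tested 19599 genes, and the biological coefficient of variation was 26.3%. CPM of single genes and of globin are relative to TMM-scaled library sizes. Summed CPM of a list are relative to unscaled total counts and include listed genes that were not tested. A ± beside a log2 change is its standard error. Gene sets were tested on log2 CPM (prior count 2) with camera of limma 3.58.1, preset inter-gene correlation 0.01. The sets were 47 gene lists, of which 46 had at least 5 tested genes, and the mouse Reactome sets of fgsea 1.28.0 with 15 to 300 tested genes. Entrez identifiers for Reactome came through GENCODE M21 and covered 78.3% of tested genes. Camera was repeated with an estimated correlation, and fry was run on the same lists. A library's score on a list is the median of its members' log2 CPM relative to the wild-type mean.

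Test design, gene lists, alternatives and the rule for naming genes were set before the data were examined. The text names Tcf23 and a fixed panel of contraction, hormone receptor and transcription factor genes. It also names the genes past the threshold with a mean CPM of at least 1 and non-overlapping groups, up to 12 per direction. Where fewer than 5 pass in a direction, it names the 5 with the smallest p at that mean CPM. From each list described it names up to 4 members with the smallest p. A gene that the rule selects is not reported here.

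The pipeline was tested on simulated data with the real means and library sizes and 200 genes changed. The changed genes were drawn only from genes of positive average log2 CPM, and genes varied independently of each other. For 3 against 3 and 19599 genes, edgeR recovered 29% of the genes changed 2-fold and 94% of those changed 4-fold, with 12.1% false calls. It made 140 calls there, against 4 in the real data. More calls make the Benjamini-Hochberg cut on p less strict, so the recovered shares need not hold for the real data. DESeq2 1.42.0 recovered 60% and 95% with 30.5% false calls, and limma-voom 30% and 95% with 12.6%. With no genotype effect and a library factor shared by the list (SD 0.5 log2), 75 of 100 lists of 35 genes passed camera with the preset correlation and 14 with an estimated one. Without that factor 3 and 1 passed. The SD was a chosen setting and was not matched to the real lists. Neutrophil scores ran from −0.19 to 0.21 in wild-type, and placental scores from −3 to 2.62 in knockout. The passing shares therefore need not hold for a given list.

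Replicates of a group differed by far more than sampling noise (chi-square per degree of freedom 35.4 to 232), so no library was counted as a duplicate. Replicate numbers are shared between the genotypes in the sample titles. The correlation across genes of deviations from the group mean was 0.147, 0.196 and 0.217 for libraries with the same number and −0.223 to 0.061 for the others. Deviations within a group cancel out, so these correlations are not independent and are weak ground for pairing. The numbers were therefore treated only as possible pairs, and what links the libraries is not stated. The main design has no block, and a fit with the replicate number as a block was an alternative.

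Other alternatives were RLE and upper-quartile scaling, no filter and a stricter filter (CPM of at least 1 in 3 libraries), DESeq2, limma-voom, a robust fit, limma on log2 of the deposited normalized values plus 1, other thresholds, glmTreat against a fold of 1.5, windows of 1 and 5 Mb, and leaving out each library. Intervals on counts cover counting error only. Of 97 genes checked under the naming rule, 33 overlap another annotated gene, and for 8 the summed counts of the overlapping genes exceed 10% of the gene's own.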

Results

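Poly(A)-selected RNA was sequenced from the myometrium, the smooth muscle layer of the uterus, of pregnant mice late in gestation (E19.5 in the sample labels, gestational day 19 in the series design). Tcf23 encodes a basic helix-loop-helix protein, and the comparison asks what its loss changes in the muscle that contracts at birth. The 6 libraries came from 3 wild-type animals and 3 animals in which Tcf23 had been knocked out with CRISPR/Cas9, 1 library per animal. Total counts were 47345181, 52733490 and 55236312 in the wild-type libraries and 65036402, 55643651 and 39939686 in the knockout libraries, and 19599 of 55055 genes had enough counts to be tested.

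Tcf23 itself (ENSMUSG00000006642, mm10 chromosome 5, 30968662 to 30977018, plus strand) was almost absent from the knockout libraries. It had 4203, 5970 and 3360 counts in the wild-type libraries, and 0, 2 and 1 counts in knockout replicates 1, 2 and 3. Relative to wild-type, the summed knockout level was 0.0213%, with an exact 95% interval for counting error of 0.00439 to 0.0623%. The fitted log2 change was −12.03, with an adjusted p of 0.000637 in edgeR's quasi-likelihood test, so the genotype labels matched the counts in 6 of 6 libraries.

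Beyond Tcf23, 3 genes were lower in knockout myometrium past the threshold. Grpr, the receptor for gastrin-releasing peptide, fell from 4.72 ± 0.303 to 0.36 ± 0.0828 CPM (mean ± SD, n = 3 per genotype), a 13-fold difference (log2 −3.70 ± 0.26 SE, edgeR adjusted p = 0.00802). Kcnk2, a background potassium channel, fell from 27.16 ± 3.45 to 7.12 ± 0.398 CPM (log2 −1.93 ± 0.15 SE, edgeR adjusted p = 0.0101). Alb, which encodes serum albumin, fell from 3.24 ± 0.521 to 0.0529 ± 0.0252 CPM (log2 −5.81 ± 0.38 SE, edgeR adjusted p = 0.00699). Counts of Kcnk2 are uncertain in part, since 4 annotated genes overlap it, 2 of them on the other strand, with summed counts of 56.4% of its own, and the strand setting of the counting is not given in the sources used here.

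**Figure D1:**
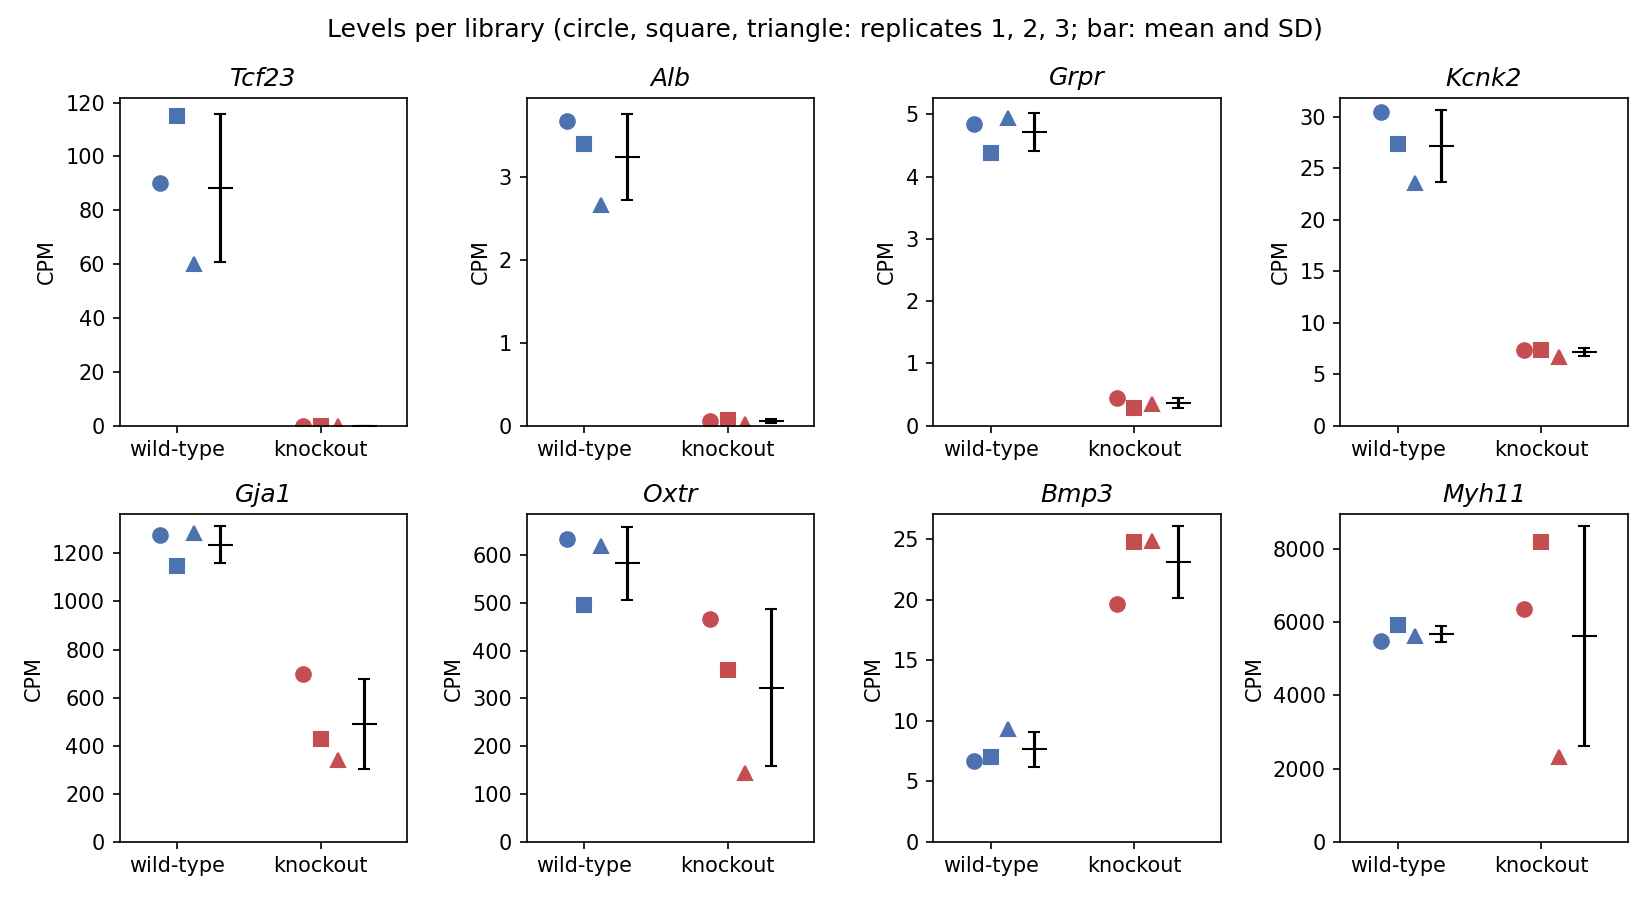
CPM per library (y axes, linear from 0) of 8 genes in wild-type (blue) and knockout (red) myometrium, with symbols for replicates and black bars for the mean and SD of 3 libraries. Tcf23, Alb, Grpr and Kcnk2 passed the edgeR threshold; Gja1, Oxtr and Bmp3 had non-overlapping groups without passing it, and Myh11 ranged from 2320 to 8190 CPM among the knockout libraries.

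No gene was higher past the edgeR threshold (0 of 19599). At an unadjusted p under 0.05, 1033 genes were higher and 645 lower, where chance alone gives 980 in all. DESeq2 on the same counts called 245 genes higher and 133 lower, among them all 4 edgeR calls. Of its 378 calls, edgeR tested 369, each with the same direction and an unadjusted p under 0.05. On simulated data of this design, DESeq2 made 30.5% false calls and edgeR 12.1%, and the share of true 2-fold changes recovered was 60% and 29%. The groups did not overlap for 14.2% of genes, where chance gives 10% on average for 3 against 3. Neither this share nor the unadjusted counts were worked out for other ways to split the libraries. An excess over chance here therefore cannot be credited to genotype.

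Among genes higher in knockout with a mean CPM of at least 1, those with the smallest p missed the edgeR threshold. They included Faim2, an inhibitor of Fas-mediated cell death (log2 2.30 ± 0.26, adjusted p = 0.0596), the growth factor gene Bmp3 (7.66 to 23.1 CPM, adjusted p = 0.0596), the cilium gene Cys1 (16.06 to 52.1 CPM, adjusted p = 0.0596) and the epithelial sodium channel subunit gene Scnn1g (log2 2.47 ± 0.31, adjusted p = 0.0902). With the same limit on mean CPM, Colgalt2, a collagen galactosyltransferase gene, was the next lower gene (15.87 to 3.72 CPM, adjusted p = 0.0567). DESeq2 called all 5 of these genes. With any 1 library left out, log2 changes stayed within −6.04 to −5.55 for Alb, −3.90 to −3.55 for Grpr and −2.03 to −1.84 for Kcnk2, while adjusted p, with fewer samples, reached 0.0738, 0.0951 and 0.145. Without wild-type replicate 1, and likewise without wild-type replicate 2, edgeR called 1 gene, Tcf23. Counts of higher genes were 1 without knockout replicate 1, 1 without wild-type replicate 3 and 3 without knockout replicate 3. Without knockout replicate 1 the adjusted p was 0.0658 for Alb and 0.07 for Kcnk2, and without knockout replicate 2 it was 0.0534 for Kcnk2. With the replicate number as a block, 2 genes were higher, Nptx1 and Car4, and 5 were lower, the fifth being Gm48874; these 3 names were chosen after their values were seen.

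Among the genes that prepare the uterus for contraction, Gja1 and Oxtr were lower in each knockout library than in each wild-type library, without passing the edgeR threshold. Gja1, the main gap junction connexin of the myometrium at term, had 1236 ± 75.4 CPM in wild-type and 489 ± 186 in knockout (log2 −1.34 ± 0.28, edgeR adjusted p = 0.237). DESeq2 gave it an adjusted p of 0.00044. The oxytocin receptor gene Oxtr had 582.7 ± 76.5 and 322.6 ± 164 CPM (log2 −0.85 ± 0.39, edgeR adjusted p = 0.611). Of the 27 tested labour-associated genes, 12 had positive and 15 negative fold changes, and 1, Gja1, passed when adjusted over the list alone, against 0 over all genes. The list as a whole did not pass camera, a competitive gene set test (adjusted p = 0.623). Ptgfr, the receptor for prostaglandin F, was 2.82 ± 1.32 and 5.25 ± 1.92 CPM, and Ptgs2, an inducible prostaglandin synthase, 4.19 ± 2.71 and 7.74 ± 2.95, with overlapping groups.

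Steroid receptor genes and transcription factors of the fixed panel did not pass. Esr1 had 540.0 ± 28.4 CPM in wild-type and 441.2 ± 18.2 in knockout, non-overlapping (edgeR adjusted p = 0.637), and Pgr 404.4 ± 40 and 281.9 ± 84.9 (adjusted p = 0.59). Log2 changes were −0.10 for Fos, 0.12 for Jun, 0.12 for Zeb1 and −0.05 for Zeb2, each with an SE of at least 0.17.

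The contractile machinery showed no genotype difference that held across libraries. Log2 changes were −0.05 ± 0.34 for Acta2, −0.16 ± 0.33 for Actg2, −0.01 ± 0.42 for Myh11, −0.07 ± 0.34 for Cnn1 and 0.17 ± 0.33 for Mylk, all near 0 relative to their SE. Of the 33 contractile apparatus genes, 12 were positive and 21 negative, and 0 passed (camera adjusted p = 0.442). The knockout libraries differed among themselves: summed smooth muscle markers were 36160, 42180 and 17030 CPM in knockout replicates 1, 2 and 3, against 29230 to 33800 in wild-type. Without knockout replicate 3 the contractile list passed as higher (adjusted p = 0.00454) and without knockout replicate 2 as lower (adjusted p = 0.00114). The smooth muscle list itself (18 genes, camera adjusted p = 0.937) passed as higher without knockout replicate 3 (0.000388). The channel genes Cacna1c and Kcnma1 had log2 changes of −0.40 ± 0.38 and −0.03 ± 0.29.

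Potassium channel genes went both ways. Of 22 tested, Kcnk2 was lower and passed over all genes, and adjusted over the list alone 1 was higher (Kcne2, 30.14 to 60.14 CPM) and 2 lower (Kcnk2, and Kcne4, 198.2 to 91.46 CPM). The list did not pass (camera adjusted p = 0.609), although it did as higher without knockout replicate 3 (0.0062). Of 32 relaxation signalling genes, the cyclic nucleotide phosphodiesterase genes Pde4d, Pde3a and Pde4b had log2 changes of −0.66, −0.71 and −0.53, and Rxfp2, a relaxin family receptor gene, 1.15. Pde4d passed adjusted over the list alone (1 lower, 0 higher), with 3 overlapping genes whose summed counts were 59.3% of its own. The list did not pass (0.442) except as lower without knockout replicate 2 (0.014).

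Most markers of 3 white blood cell groups had positive fold changes in knockout myometrium, and the 3 lists passed camera with a preset correlation but not with an estimated one (adjusted p = 0.398, 0.398 and 0.568, in the order below). Of 35 natural killer and T cell genes, 32 had positive fold changes, with a median log2 change of 0.85, 12 higher and 0 lower when adjusted over the list alone and 0 over all genes. Il2rb, an interleukin receptor subunit gene, went from 3.15 to 7.69 CPM. Neutrophil genes were positive in 13 of 15 (median 1.02, 9 higher adjusted over the list alone, 0 over all genes), led by the calprotectin genes S100a9 (0.653 ± 0.236 to 4.66 ± 3.03 CPM; log2 2.83, and 2.16 without knockout replicate 1) and S100a8 (0.648 ± 0.226 to 3.32 ± 1.84 CPM). B and plasma cell genes were positive in 17 of 19 (median 0.92, 2 higher adjusted over the list alone, 0 over all genes), with the immunoglobulin constant region genes Igha (131.9 ± 79.7 to 561 ± 347 CPM; log2 2.09, and 1.458 without knockout replicate 2) and Igkc (75.06 ± 47.1 to 290.9 ± 136 CPM) among the 4 with the smallest p. Reads of the related immunoglobulin genes can be shared between them, which makes single values uncertain. By camera with a preset correlation, adjusted p was 5.2e-13, 3.02e-09 and 7.47e-08 for the 3 lists. By fry, which makes no comparison with other genes, the adjusted p for a shared direction was 0.0857, 0.0857 and 0.335, so none of the 3 passed, and for change in either direction it was 0.00285, 0.00473 and 0.0834. Summed CPM overlapped between genotypes for natural killer and T cells (135.1, 44.77 and 41.31 in knockout replicates 1, 2 and 3, and 34.68, 28.31 and 63.44 in wild-type). Sums also overlapped for neutrophils (2255, 2033 and 3786, and 2138, 1136 and 2749), and not for B and plasma cells (1122, 1970 and 1040, and 448.9 to 665.4). By replicate number, which marks only possible pairs, each knockout neutrophil sum was the higher. The natural killer and T cell sum was lower in knockout replicate 3. Members more abundant than the leading genes carry the neutrophil sum. S100a9, S100a8 and Csf3r had 4.66, 3.32 and 13.4 CPM in knockout, so the overlap does not bear on them.

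Most mast cell markers had negative fold changes. Of 13 genes, 12 were negative (median log2 −0.95; camera adjusted p = 3.24e-06, and adjusted p = 0.568 with an estimated correlation), with 3 lower and 1 higher adjusted over the list alone and 0 over all genes. The mast cell tryptase gene Tpsab1 went from 2.93 to 1.02 CPM, and the receptor genes Mrgprb1 and Mrgprb2 had log2 changes of −1.31 and −1.21. The exception was Hdc, whose enzyme makes histamine, at 4.24 and 8.56 CPM; it is also on the neutrophil list. The genotypes were not clearly separated in the list's score. It was −0.31, −1.31 and −1.55 in knockout replicates 1, 2 and 3 and −0.15, 0.49 and −0.31 in wild-type replicates 1, 2 and 3. Summed CPM overlapped (170.5, 130.4 and 111.7 in knockout, and 181.9, 252.4 and 170.2 in wild-type). By replicate number, which marks only possible pairs, each knockout score and sum was the lower.

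**Figure D2:**
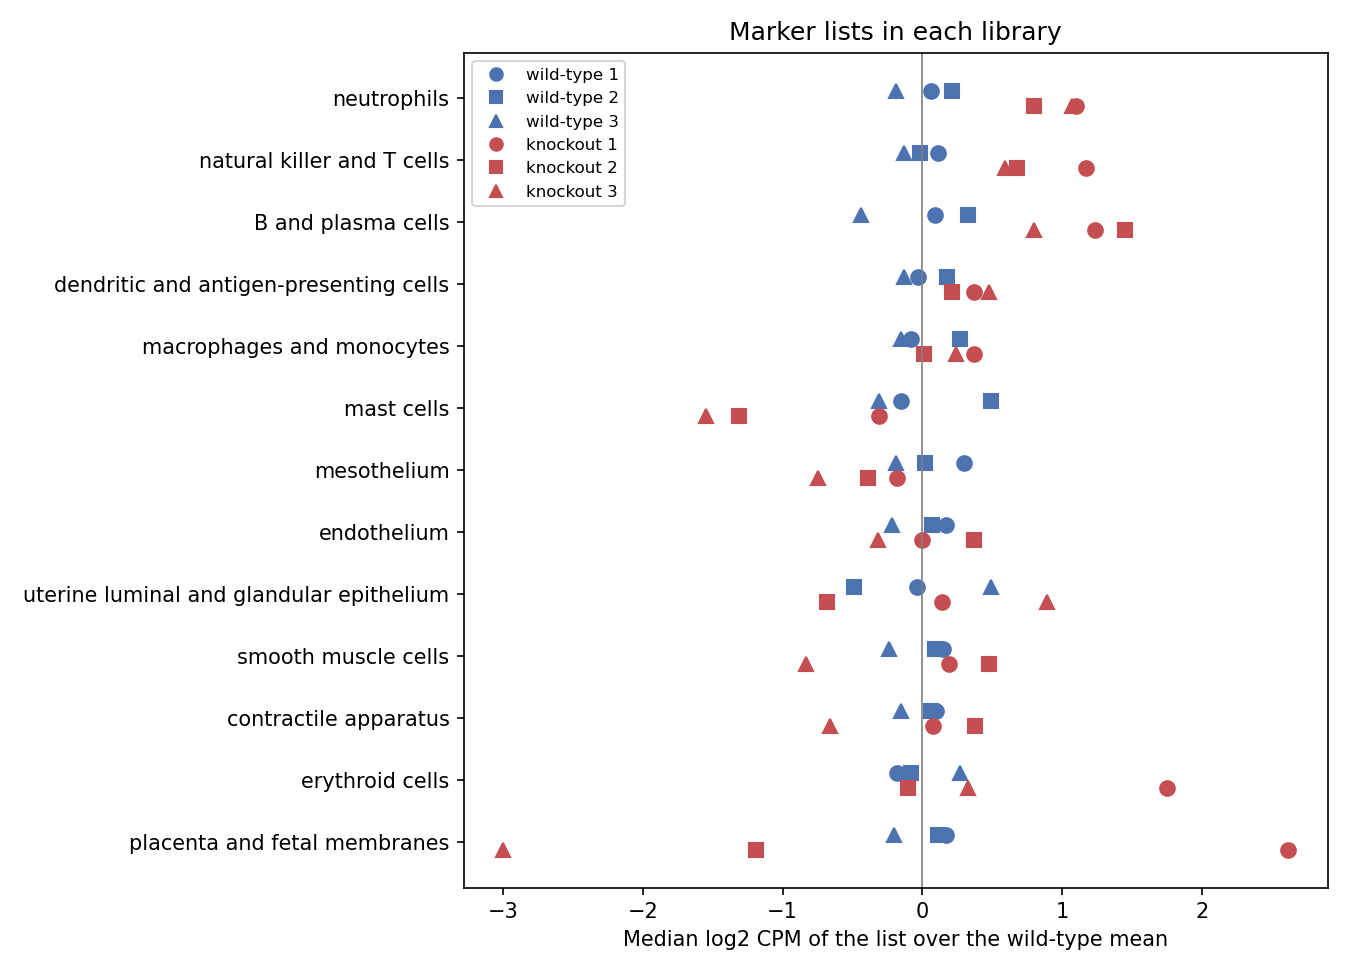
Median log2 CPM of each marker list, relative to the wild-type mean (x axis), in the 3 wild-type (blue) and 3 knockout (red) libraries, with a symbol per replicate. The neutrophil scores were 1.10, 0.80 and 1.07 in the knockout libraries, all above the wild-type maximum of 0.21, whereas the placental scores ran from −3 to 2.62 among the knockout libraries.

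Most genes of 3 lists for defence and inflammation had positive fold changes, and the lists passed camera with the preset correlation but not with an estimated one (adjusted p = 0.568 for each). All 19 tested genes for uterine secretions and antimicrobials were positive (median log2 0.93, 4 higher adjusted over the list alone, 0 over all genes; camera adjusted p = 1.8e-05), among them Defb1, a defensin gene (3.27 to 11.6 CPM), and the chitinase-like genes Chil1 and Chil3. This list's scores were 1.17, 0.39 and 1.01 in knockout replicates 1, 2 and 3, beside uterine epithelium scores of 0.14, −0.68 and 0.89, and in wild-type they were 0.13, −0.32 and 0.36 beside −0.04, −0.49 and 0.49. Of 40 inflammatory cytokine and chemokine genes, 32 were positive (median 0.32, 3 higher adjusted over the list alone, 0 over all genes; camera adjusted p = 0.00067). Its leading members were Cxcl5, Ccl3 and Csf1, and Csf1, the macrophage growth factor gene, went from 420.7 to 1062 CPM. All 18 dendritic and antigen-presenting cell genes were positive (median 0.39, 0 adjusted over the list alone or over all genes; camera adjusted p = 3.11e-05). The inflammatory list was lost without knockout replicate 1 (0.276).

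The other 7 lists that passed had smaller or less even shifts, 0 calls over all genes, and 0 to 1 calls adjusted over the list alone. The higher ones were interferon response (34 of 37 genes positive, median log2 0.17, adjusted p = 0.00256), macrophages and monocytes (21 of 26, 0.20, 0.00619; 1 call adjusted over the list alone, Cx3cr1, uncertain because 9 genes overlap it with summed counts of 549% of its own), skeletal muscle (12 of 14, 0.40, 0.0273), prostaglandin synthesis and turnover (16 of 21, 0.28, 0.029), matrix-degrading enzymes and inhibitors (19 of 27, 0.16, 0.029) and erythroid cells (9 of 11, 0.81, 0.0307). Cholesterol and lipid synthesis was lower (21 of 27 negative, −0.21, 0.00625), led by Idi1 and Srebf2. With an estimated correlation the adjusted p was 0.568 for the prostaglandin list and 0.977 for the other 6. Each was lost without at least 1 library. Without knockout replicate 1 the adjusted p was 0.276 for interferon response, 0.234 for skeletal muscle, 0.271 for prostaglandins, 0.324 for matrix-degrading enzymes and 0.728 for erythroid cells. Without knockout replicate 2 it was 0.472 for cholesterol synthesis, 0.311 for matrix-degrading enzymes and 0.177 for skeletal muscle, and without knockout replicate 3 it was 0.0574 for macrophages and 0.0568 for prostaglandins. Without wild-type replicate 1 it was 0.0694 for macrophages, 0.109 for skeletal muscle, 0.0642 for prostaglandins and 0.311 for erythroid cells. Without wild-type replicate 2 it was 0.108 for interferon response, 0.0801 for prostaglandins and 0.093 for erythroid cells, and without wild-type replicate 3 it was 0.128 for macrophages, 0.0558 for cholesterol synthesis, 0.0923 for skeletal muscle and 0.128 for matrix-degrading enzymes. The erythroid list was also lost with the replicate block (0.0886) and, as was the matrix-degrading list (0.0923), with a stricter count filter (0.0651).

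**Figure D3:**
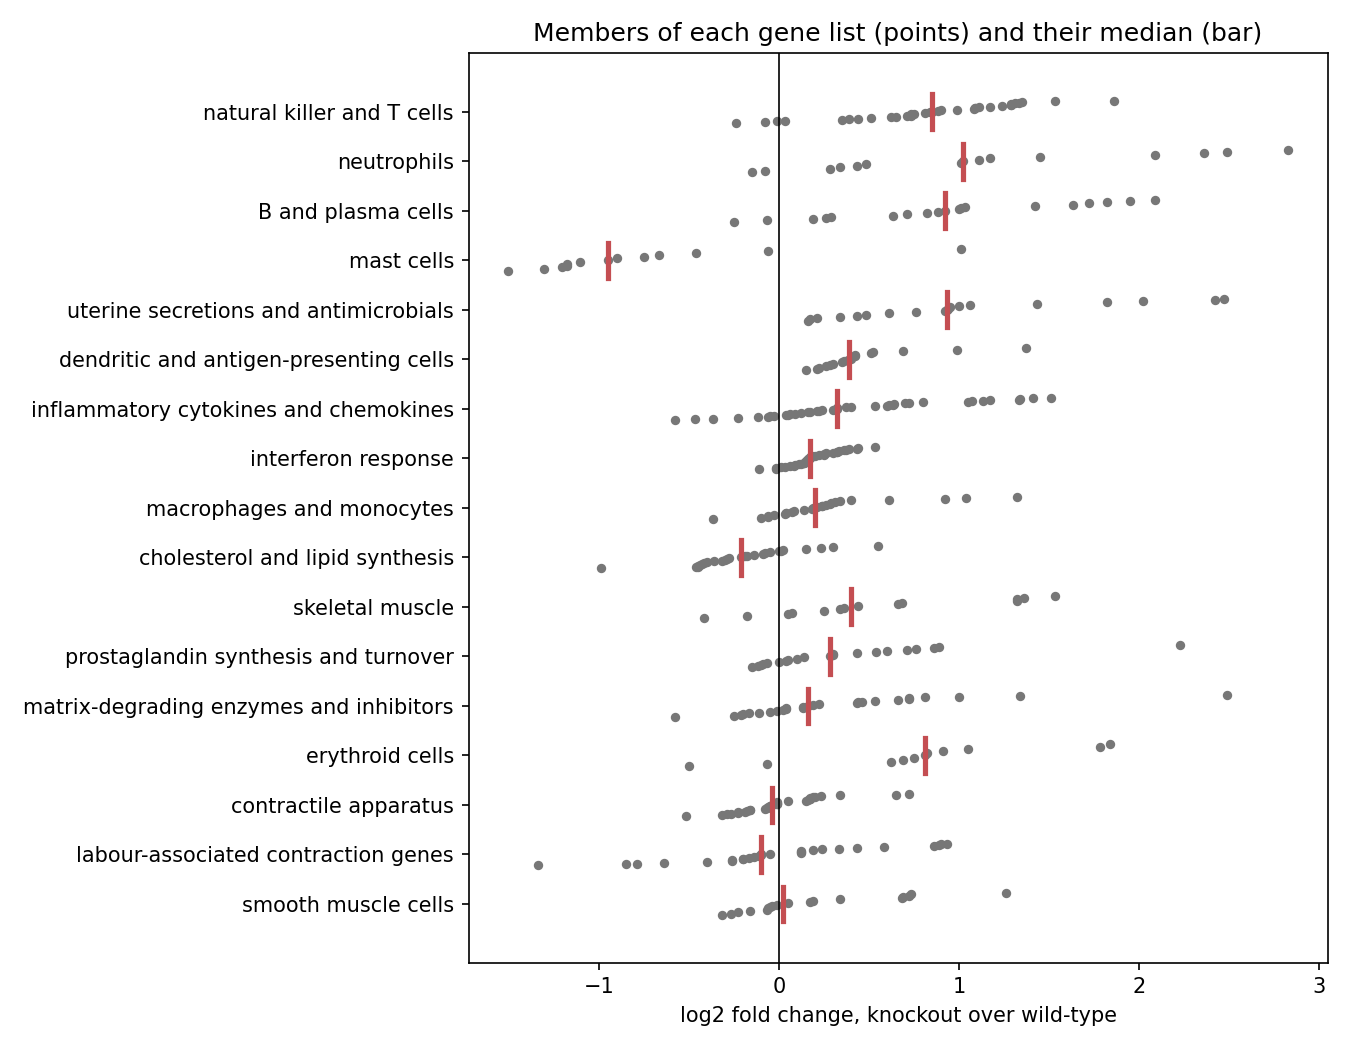
Fitted log2 fold change, knockout over wild-type (x axis), of each tested gene (grey points) in the 14 lists that passed camera and 3 muscle lists that did not, with the median of each list as a red bar. The medians of the neutrophil and mast cell lists are 1.02 and −0.95, and those of the contractile and smooth muscle lists −0.04 and 0.02.

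In all, 14 of 46 tested lists passed with the preset correlation and 0 with an estimated one. The number of lists does not set the genotype comparison apart, because 7 of the other 9 ways to split the 6 libraries into 3 and 3 passed more lists, up to 23. Libraries also differed in tissue content within the knockout group. Summed placental and fetal membrane markers were 1090 CPM in knockout replicate 1, 150.9 in replicate 2 and 62.47 in replicate 3, against 132.3 to 181.9 in wild-type. That list (34 genes) had a median log2 change of 1.46 while camera gave the direction as lower (adjusted p = 0.267), and it passed as lower without knockout replicate 1 (4.37e-09). Of 20 mesothelial genes, 10 were positive and 10 negative, and 1, Msln, was lower adjusted over the list alone (59.69 to 19.91 CPM). The list had a camera adjusted p of 0.248, and of 0.000792 as lower without wild-type replicate 3.

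Growth factor signalling genes had fold changes of both signs. Of 35 TGF-beta and BMP genes, 16 were positive and 19 negative; 5 were higher and 7 lower at an unadjusted p under 0.05, 2 higher and 0 lower adjusted over the list alone, and 0 over all genes. Fry's test for change in either direction gave the list an adjusted p of 0.000138. This is not particular to the list, since 9 of 46 lists passed that test and the fibroblast list had the same value. Grem1, a BMP antagonist gene, went from 0.0386 to 0.707 CPM (log2 4.11 ± 0.44, edgeR adjusted p = 0.0567), and Tgfb2 from 170.6 to 535.5 CPM (log2 1.65 ± 0.26, adjusted p = 0.143). Inhba, an activin subunit gene, had a log2 change of −1.30 and Bmpr1a of −0.58. The list did not pass camera (0.525), which tests for a shared direction; its median log2 change was −0.07 and its mean 0.08.

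Of 706 Reactome pathways, 5 passed camera, all higher in knockout, and 0 with an estimated correlation (smallest adjusted p = 0.997). They were immunoregulatory interactions between lymphoid and non-lymphoid cells (45 of 53 genes positive, adjusted p = 7.83e-06), generation of second messenger molecules (0.0075), chemokine receptor binding (0.00924), the endosomal vacuolar pathway (0.045) and collagen degradation (34 of 50 positive, 0.0464). The other 9 splits of the libraries passed 15 to 223 pathways, all more than the genotypes. The number was 151 without knockout replicate 1, 24 without knockout replicate 2, 29 without knockout replicate 3, 11 without wild-type replicate 2 and 3 without wild-type replicate 3, and 3 with the replicate block.

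Genes around the edited locus did not stand out. Of 64 tested genes within 2 Mb of Tcf23, 0 passed the edgeR threshold and 4 had an unadjusted p under 0.05, or 6.25% against 8.56% of genes elsewhere (two-sided Fisher's exact p = 0.657). DESeq2 called 1 of the 64, Dpysl5 (4.78 to 12.9 CPM, DESeq2 adjusted p = 4.66e-07, edgeR adjusted p = 0.117), named here because of its value. The shares of mitochondrial counts (2.26 ± 0.272% and 2.44 ± 0.41%), of the 10 most abundant genes (8.53 ± 0.431% and 8.63 ± 0.555%) and of ribosomal protein genes (2.70 ± 0.12% and 2.69 ± 0.698%) differed by less than the spread between libraries in wild-type and knockout (n = 3 each; two-sided exact permutation p = 0.7, 0.9 and 1, where 0.1 is the smallest possible).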

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

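Tcf23 stayed below wild-type past the threshold in all fits run (log2 −12.85 to −11.21). Genes higher in knockout numbered 0 in the main fit and 245 with DESeq2, 47 with no low-count filter, 4 with upper-quartile scaling, 7 at adjusted p under 0.1, and 2 with the replicate block. Genes lower numbered 4, against 133, 34, 8 and 10 in the first 4 of these. In fits added after seeing the data, 1 gene was higher with the newer quasi-likelihood fit, with the smooth muscle score as a covariate and with the placental score as a covariate. Leaving out 1 library gave 0 to 3 higher genes, 1 to 4 lower genes and 3 to 151 Reactome pathways, against 5 in all 6 libraries. No list and no pathway passed with an estimated correlation or with fry's directional test (0 each); fry's test for change in either direction passed 9 lists. The number of pathways was 2 with the stricter filter and 3 with the replicate block. The block changed no other call beyond those in the report. The cause of these differences was not tested, except that leaving out libraries leaves fewer samples. The legacy quasi-likelihood fit listed among the alternatives is the default of the edgeR version used, so it was not a separate fit.

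Named genes with small changes crossed 0 when 1 library was left out: log2 ran from −0.28 to 0.24 for Acta2, −0.39 to 0.13 for Actg2, −0.35 to 0.24 for Cnn1, −0.21 to 0.032 for Fos, −0.021 to 0.27 for Jun, −0.42 to 0.14 for Kcnma1, −0.39 to 0.36 for Myh11 (0.024 with upper-quartile scaling), −0.16 to 0.44 for Mylk, −0.15 to 0.30 for Zeb1 and −0.34 to 0.16 for Zeb2. Lists that changed direction had adjusted p of 0.00114 to 0.704 (contractile apparatus), 0.21 to 0.795 (labour-associated), 4.37e-09 to 0.511 (placenta), 0.0062 to 0.94 (potassium channels), 0.014 to 0.827 (relaxation signalling) and 0.000388 to 0.807 (smooth muscle) over those fits. With fry the potassium channel (0.995) and TGF-beta (0.998) lists changed direction. Share differences ran from −0.0597 to 0.308 percentage points for mitochondrial counts, −0.113 to 0.416 for the top 10 genes and −0.355 to 0.342 for ribosomal protein genes. Over all alternatives of 96 genes under the naming rule, Tcf23 left out, 1440 values kept direction and side of the threshold, 57 passed in addition and 9 no longer passed. Depth was 39939686 counts or more per library, and libraries of 1 genotype differed with a variance of at least 35.4 times that of counting error (chi-square per degree of freedom).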

Other observations

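The tests of explanations below were chosen after the results were seen, except the counts of library splits. The criterion for placental or decidual tissue was also made stricter after its values were seen, by adding summed markers and Y-linked counts to the placental score; by the score alone this source had been argued against, and by the stricter criterion it is open.

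Genotype gave 4 genes past the threshold, and the highest of the other 9 splits of the 6 libraries gave 0; 1 of 10 splits was as large, and 10 splits cannot give a share under 0.05. For gene lists the real value was 14 and the highest other 23, and 8 of 10 splits were as large. For Reactome pathways these values were 5, 223 and 10 of 10. Among the 3 other splits that part each same-numbered pair, 0 genes, 8 to 22 lists and 15 to 221 pathways passed. Splits that pass many more sets than the genotypes point to a structure of the samples apart from genotype; what it is was not tested, and the placental and smooth muscle marker levels of the knockout libraries are given in the report.

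Higher immune-cell markers in knockout were weighed against 3 sources in the tissue. A smaller share of smooth muscle is argued against in knockout replicates 1 and 2. Their smooth muscle scores (0.19 and 0.48) were above the wild-type range of −0.24 to 0.15. In knockout replicate 3 the score was −0.83, and this source cannot be told apart. Immune scores exceeded endothelial scores by at least 0.303 log2 in each knockout library. Endothelial scores were also lowest in knockout replicate 3 (−0.32), so that comparison cannot decide for it. Carried-over placental or decidual tissue cannot be told apart. Knockout replicate 3 had low placental markers (62.47 CPM, and 132.3 to 181.9 in wild-type) while each natural killer and T cell, neutrophil and B cell score was at least 0.468 log2 above the highest wild-type score, but this is 1 library. In knockout replicate 2 the placental score was below the wild-type range, yet summed placental markers (150.9 CPM) lay inside it and Y-linked genes, which mark male fetuses, had 32 counts, against 60 and 3 in knockout replicates 1 and 3 and 4 to 13 in wild-type. Of 25 tested genes on the decidual list, 3 were higher in each knockout library than in each wild-type library. Among them were Adamdec1 (2.51 to 17.07 CPM, log2 2.77) and Prl8a2 (10.45 to 58.89 CPM, log2 2.49). In the other direction, 1 gene, Htra3, was lower in each knockout library (960.7 to 633.5 CPM, log2 −0.60). The groups did not overlap for 14.2% of all tested genes, so these counts do not set the decidual list apart. It did not pass camera (adjusted p = 0.816 with the preset correlation). The list's scores were 0.19, 0.22 and −0.41 in knockout replicates 1, 2 and 3 and −0.09 to 0.18 in wild-type. Blood in the tissue cannot be told apart in knockout replicate 1, with globin at 274.2 CPM, against 49.47 to 103.3 in wild-type. In knockout replicates 2 and 3 globin (72.7 and 99.5 CPM) lay inside that range. Their scores on the 3 immune lists were 0.59 to 1.45, and the highest wild-type score was 0.33. Wild-type replicate 3 had the most globin in wild-type and scores of −0.13, −0.19 and −0.44. These values argue against blood for knockout replicate 2, where globin was −0.04 log2 over the wild-type mean and the lowest immune score 0.68. In knockout replicate 3 globin was 0.41 log2 over that mean, close to the lowest immune score of 0.59, so blood cannot be told apart there. The second lowest of the 3 knockout differences between globin and immune scores, −0.178 log2, is within the wild-type spread, so that test alone could not tell. An effect of genotype on immune cells is therefore open, as are differences between animals, and with an estimated correlation no list passed.

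Lower Gja1 was weighed against muscle content and stage. After the smooth muscle score was subtracted, the highest knockout library was still 0.823 log2 below the lowest wild-type library (difference −0.823), which argues against a smaller share of smooth muscle. An earlier stage before labour in the knockout animals cannot be told apart, because the other 26 labour-associated genes went both ways (12 positive, camera p = 0.802 with the preset correlation and 0.869 with an estimated one).

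A hypothesis came from single genes: 5 receptor genes whose products drive smooth muscle contraction had negative fold changes, Grpr (log2 −3.70), Agtr1a (−2.35), Tacr1 (−2.29), Lpar1 (−1.11) and Oxtr (−0.85), and loss of Tcf23 may lower such receptors as a class. Agtr1a, Tacr1 and Lpar1 were named after their values were seen (edgeR adjusted p = 0.103, 0.215 and 0.113). The other 23 tested receptors of this kind, listed after those 5 were noticed and after the values of some, Ptgfr among them, had been seen, did not bear this out: 14 were positive, the median log2 change was 0.10, and camera gave the direction as higher (p = 0.105, and 0.226 with an estimated correlation). The class hypothesis is undecided by this test.

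The mesothelial gene Upk3b had 59.83, 21.37 and 2.94 CPM in wild-type replicates 1, 2 and 3 and 2.38 to 5.73 CPM in knockout. Summed markers of the mesothelial list were 9425, 8273 and 14880 CPM in those wild-type libraries and 10620 to 23060 in knockout. Upk3b and Msln (59.69 CPM in wild-type, 19.91 in knockout) are a small part of that sum. More abundant members carry it, and Igfbp5, another member, was higher in knockout (663.1 to 1067 CPM). The sum therefore does not show how mesothelial content differed. Trophoblast gene Tpbpa had 243.7 CPM in knockout replicate 1, 0.244 in knockout replicate 3 and 9.23 to 33.11 in wild-type.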
